A study of Sus scrofa with 12 samples.

How the data were processed

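Duodenal mucosa of 12 pigs (Sus scrofa), each 140 days old, was profiled on 12 Affymetrix Snowball arrays, 1 array per pig. The labels give feed efficiency (FE, how well feed is turned into growth) as high or low, sex, and a pig identifier. There were 6 pigs per FE group and 3 of each sex in each group. Total RNA was extracted with Qiazol and RNeasy columns, made into cDNA with an Ambion WT Expression Kit and biotin-labelled with Affymetrix reagents, per the labels. GCOS 1.1.1 is named in the submitters' processing notes. The background correction, the normalization and the summarization of probes into probe sets are not given in the sources used here.

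The deposited values were on a log2 scale, from 0.21 to 14.21 over 47845 probe sets, and were used as deposited. This scale was read from the values and is not stated in the labels. The medians of the 12 arrays lay between 3.83 and 3.91, and the distributions were not identical between arrays. No 2 arrays held the same values, since correlations between arrays lay between 0.917 and 0.965. The 123 control probe sets were left out of every test. Among them are 69 antigenomic background probe sets, which match no pig transcript. Their median per array, between 2.16 and 2.53, served as the measure of array background. Means of single background probe sets over the 12 arrays ranged from 1.21 to 7.62. A level above those medians therefore does not by itself show a transcript. The number of arrays limits the precision of every value.

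Gene symbols came from the platform annotation of the array, which can be old. Of all probe sets, 26426 had 1 symbol, 0 had several and 21296 probe sets other than controls had none and are unnamed here. An array symbol that is a synonym of 1 gene in the Sscrofa11.1 gene table took that gene's symbol, unless a gene list uses the array's name. This changed 169 of 13755 symbols. Coordinates were not used here, because no build is named for the array.

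Probe sets with a mean over the 12 arrays above the 30th percentile, a log2 value of 2.37, were kept. The 33405 probe sets kept were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with default settings), with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. One model held FE and sex, and gave the difference between high and low FE and that between males and females. A model with a mean for each of the 4 combinations of FE and sex gave the interaction and the FE difference within each sex. Differences are high minus low FE or male minus female.

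Gene lists for epithelial, immune, stromal, metabolic and signalling functions, and for tissues next to the mucosa, were fixed before the data were examined. Each gene was represented by its probe set with the highest mean, over 12266 genes. Of 47 lists, 46 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. The list of Y-linked genes had 1 measured gene and was not tested. Each list's mean log2 value per pig was its score. Scores were compared between FE groups by a two-sided exact permutation test within sex, over 400 assignments, whose smallest p is 0.005.

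The genes named follow a rule fixed beforehand. For FE, these are the 12 highest-ranked higher and 12 lower genes with the same sign in both sexes, ranked first by passing the threshold, there by size, and then by unadjusted p. Each gene is represented by its brightest probe set. For sex, the rule takes 8 and 8 with the same sign in both FE groups, for the interaction 5 and 5 and within each sex 4 and 4, and it adds Y-linked genes and XIST as a check of the sex labels. From each list described it takes the members past the threshold over all probe sets or over the list alone, at most 6, or otherwise the 2 with the lowest unadjusted p. Genes and probe sets outside this rule are said to be so.

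The fits were tested on simulated data with the real means and residual spreads. Probe sets were drawn independently of each other, and 50 were changed at once at each size of 0.5, 1, 2 and 4. For the FE difference over 33405 probe sets, 18% of differences of 0.5, 66% of differences of 1 and 94% of differences of 2 on the log2 scale were recovered. For the interaction, 8% of differences of 1 and 54% of differences of 2 were recovered. The many large differences make the adjusted threshold easier to pass. These shares are therefore not the power of the real tests where few genes differ.

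Alternatives fixed beforehand changed the filter, the normalization, the variance model, the weights of arrays, the linear model, the number of probe sets per gene, the threshold, the model terms and the set of pigs. Added after the data were seen were the array background as a term, the score of the Brunner gland and gastric-type list as a term, the named genes under the filters, the ordinary linear model and 1 probe set per gene symbol, and a fit without the 3 arrays lowest on the first principal component, which are those of high FE pigs 1, 2 and 5 and leave 3 pigs in that group. No label gives a batch. The pig identifiers fall into 2 runs, which stood in for one as an additional term. Within each run the identifiers of the high FE pigs come before those of the low FE pigs. A finer difference along the identifiers therefore cannot be told apart from FE. The second run holds 4 females and no males, so this term is largely confounded with sex.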

Results

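The series compares the duodenal mucosa of pigs that differ in feed efficiency. Each of the 12 arrays came from a separate pig aged 140 days, with 6 pigs of high and 6 of low FE, and 3 males and 3 females in each group. All values below are log2 values as deposited, with SD over pigs or SE of a difference from the limma model.

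No gene passed the threshold between high and low FE. Among the 12 genes ranked highest with more signal in high FE, CHEK1, a checkpoint kinase, had 3.46 ± 0.49 (SD, n = 6) in high FE and 2.60 ± 0.44 (SD, n = 6) in low FE, close to the array background. CDC25A, a phosphatase that drives the cell cycle, had 5.85 ± 0.04 and 5.45 ± 0.18. TSR1 and AATF, which act in the assembly of the small ribosomal subunit, differed by 0.44 ± 0.11 (SE) and 0.45 ± 0.10 (SE), and MRPS30 of the mitochondrial ribosome by 0.61 ± 0.13 (SE). None of these 5 genes passed, with an adjusted p of 0.753 each.

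The other genes ranked with more signal in high FE were MIP, RAP1GDS1, STOML3, FAIM, KCNAB1, EFNB2 and PHF14. MIP, a water channel of the lens, differed by 1.27 ± 0.20 (SE), with an adjusted p of 0.504, at a level of 2.51 ± 0.56 (SD, n = 6) in low FE. That level is close to the array background. RAP1GDS1, a regulator of small GTPases, differed by 0.97 ± 0.20 (SE) and had 6.69 ± 0.33 in high FE.

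Among genes with less signal in high FE, HSPB6, a small heat shock protein of smooth muscle, had 8.03 ± 0.24 (SD, n = 6) in high FE and 8.71 ± 0.41 (SD, n = 6) in low FE. SOSTDC1, a secreted antagonist of BMP and WNT signals, differed by -0.91 ± 0.24 (SE), and TNFSF15, a cytokine of the TNF family, by -0.51 ± 0.13 (SE). MMACHC, which handles vitamin B12 in the cell, differed by -0.54 ± 0.15 (SE). SAMD11, AHNAK2, GRIK3, TMEM185A, NDP, NPAS1 and 2 genes with locus names only complete the 12. All had an adjusted p of 0.753. For NDP, its 2 other probe sets differed in the opposite direction.

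Of 33405 probe sets, 0 passed an adjusted p of 0.05 or 0.1 in limma, where the smallest was 0.307, and 0 passed in an ordinary linear model. At an unadjusted p under 0.05 there were 2000, of which 884 were higher and 1116 lower in high FE. About 1670 are expected by chance.

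Smooth muscle genes formed the list with the lowest p for FE. Of its 21 measured genes, 17 had lower means in high FE, with a median difference of -0.32, and the list passed camera's test with an adjusted p of 0.00219. That call was lost with an estimated correlation between genes (adjusted p = 0.985 with an estimated correlation) and without high FE pig 4, at an adjusted p of 0.0531. With the estimated correlation, the adjustment gave this same 0.985 to all 46 lists for FE, so it does not tell the lists apart. HSPB6 and CASQ2, a calcium-binding protein of muscle, were the 2 members that passed when adjusted over the list alone, each with an adjusted p of 0.0401. With the array background as a term the list's median was -0.18. None of its members passed over all probe sets. CASQ2 had 4.38 ± 0.19 (SD, n = 6) in high FE and 5.10 ± 0.47 (SD, n = 6) in low FE. Other lists of the gut wall were lower in high FE without passing, with 24 of 29 fibroblast and extracellular matrix genes (median -0.17, adjusted p 0.0702), 13 of 16 genes of enteric neurons and glia (-0.10, 0.40) and 11 of 13 adipocyte genes (-0.19, 0.111) at lower means. Blood and lymphatic endothelium had 16 of 26 genes lower (-0.04, 0.868). Most lists of other functions that did not pass also had a negative median, and fewer a positive one. The median difference over all 33405 probe sets was -0.02. Lower were 25 of 32 genes of the growth hormone, IGF and insulin axis and 19 of 24 of antimicrobial defence, and 21 of 29 T and NK cell genes were higher. Lower means were therefore not particular to the gut wall.

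Of 34 oxidative phosphorylation genes, 30 had lower means in high FE, with a median of -0.15 and an adjusted p of 0.00498 (adjusted p = 0.985 with an estimated correlation). COX6A1, a subunit of cytochrome oxidase, differed by -0.43 ± 0.15 (SE), and NDUFS4 of complex I by -0.45 ± 0.17 (SE). Of 30 genes of fatty acid oxidation and ketogenesis, 24 were lower, with a median of -0.14 and an adjusted p of 0.0273 (adjusted p = 0.985 with an estimated correlation). BDH1, which interconverts ketone bodies, had 7.08 ± 0.48 (SD, n = 6) in high FE and 7.74 ± 0.23 (SD, n = 6) in low FE, and SLC25A20, the carnitine carrier of mitochondria, differed by -0.46 ± 0.18 (SE). No member of either list passed by itself or when adjusted over the list alone. The oxidative phosphorylation call ended without low FE pig 1 (adjusted p 0.0688) or high FE pig 5 (0.0545). It also ended without the 3 arrays lowest on the first principal component (0.48), where its median was 0.0159. With the Brunner gland score as a term its median was -0.23. The fatty acid oxidation call ended without high FE pig 1 (0.0725), high FE pig 4 (0.0531), low FE pig 1 (0.196) or low FE pig 5 (0.0844), without those 3 arrays (0.253, with a median of -0.0407), and with the mean of all probe sets of a gene (0.0516), and its median was -0.22 without low FE pig 3.

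Goblet cell and mucus genes had lower means in high FE for 14 of 16 members, with a median of -0.23 and an adjusted p of 0.0273 (adjusted p = 0.985 with an estimated correlation). TFF3, the trefoil peptide of goblet cells, had 9.84 ± 0.46 (SD, n = 6) in high FE and 10.38 ± 0.40 (SD, n = 6) in low FE, and BCAS1 differed by -0.51 ± 0.21 (SE). Cell proliferation was the 1 list that passed with higher values in high FE, where 24 of 38 genes were higher, with a median of 0.05 and an adjusted p of 0.0273 (adjusted p = 0.985 with an estimated correlation). CDC6, which licenses DNA replication, differed by 0.53 ± 0.16 (SE) and PCNA, the replication clamp, by 0.45 ± 0.17 (SE). The goblet cell call ended without high FE pig 1, 3, 4 or 6 or low FE pig 3, 4 or 6, with adjusted p up to 0.124, with quantile normalization of the arrays, at 0.0933, and with the score of Brunner gland and gastric-type genes as a term, at 0.52. The proliferation call ended without high FE pig 1, 3 or 4 or low FE pig 3 or 6, with adjusted p up to 0.336, with the array background as a term, at 0.262, and with the Brunner gland score as a term, where the median was -0.0567. Its median moved by over 1.5 times without high FE pig 1, 2, 4, 5 or 6 or low FE pig 1, from -0.0035 without high FE pig 4, a turned sign, and 0.0082 without high FE pig 1 to 0.147 without high FE pig 2, and was 0.118 without the 3 arrays lowest on the first principal component.

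Pancreatic acinar genes also passed, with lower means in high FE for 15 of 16 members, a median of -0.52 and an adjusted p of 0.0273 (adjusted p = 0.985 with an estimated correlation). Low FE pig 6 set this value. Its score was 7.36, and those of the 11 other pigs lay between 4.86 and 5.13. Without low FE pig 6 the median was -0.10 and the adjusted p 0.206. The call also ended without high FE pig 3, 4, 5 or 6, with adjusted p up to 0.136, with the median filter, at 0.16, with the array background as a term, at 0.307, and with the Brunner gland score as a term, at 0.149, with medians of -0.30, -0.17 and -0.29. PNLIP, pancreatic lipase, and SYCN of zymogen granules differed by -1.05 ± 0.51 (SE) and -0.30 ± 0.14 (SE), where the PNLIP mean in high FE, 2.04, lies under the background medians. PNLIP stood at 6.17 in low FE pig 6 and at most at 2.99 in the other pigs. Over the alternatives its difference lay between -1.23 and -0.48, and that of SYCN between -0.36 and -0.19.

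**Figure D1:**
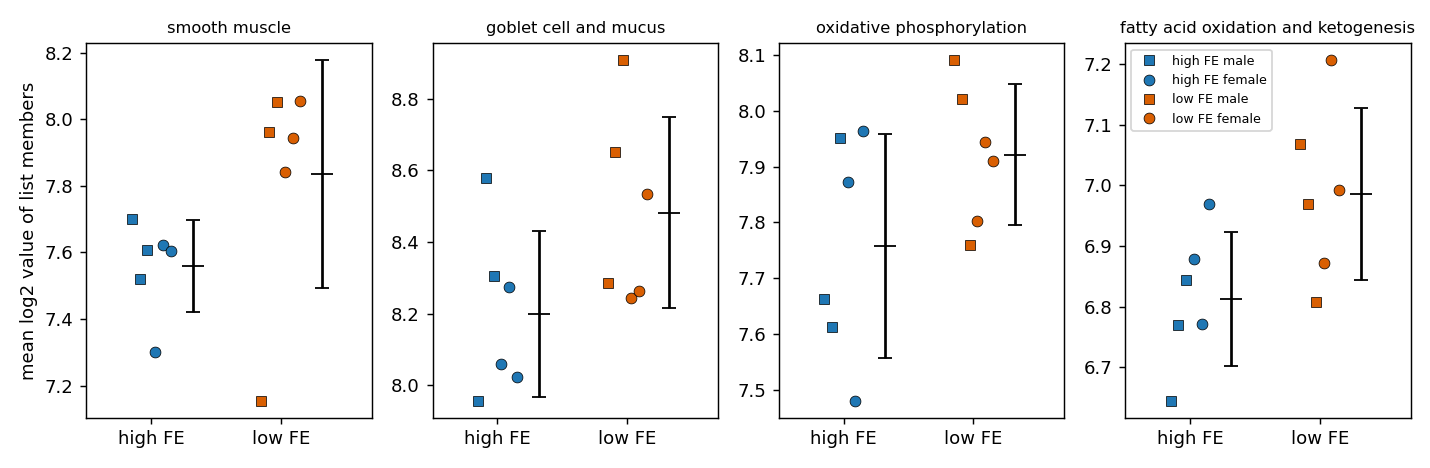
Scores of 4 gene lists in high and low FE pigs, as the mean log2 value of the list's members on the vertical axis; each point is a pig (squares males, circles females) and the bar beside each group is its mean with the SD. For smooth muscle the group means are 7.56 in high FE and 7.84 in low FE, and the points of the groups overlap in all 4 lists.

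The lists of nutrient absorption did not pass. Medians were -0.01 for lipid absorption and chylomicron assembly over 27 genes, -0.04 for carbohydrate digestion and sugar transport over 17, -0.05 for peptide digestion and amino acid transport over 27 and 0.01 for mineral and vitamin absorption over 24, with adjusted p between 0.868 and 0.966. The mean was 0.09 for the carbohydrate list and -0.0053 for the mineral list, opposite in sign to their medians, and camera's direction was up for the carbohydrate and peptide lists, whose medians were negative. Their members with the lowest p included AGPAT2, which makes phosphatidic acid, at -0.59 ± 0.27 (SE), SLC2A1, a glucose transporter, at -0.35 ± 0.14 (SE), SLC7A6, an amino acid transporter, at 0.32 ± 0.16 (SE) and MT1A, a metallothionein, at -0.53 ± 0.19 (SE). The mature enterocyte list, with a median of -0.10 over 15 genes, had an adjusted p of 0.868. The interferon response list, with a median of -0.04 over 36 genes, had an adjusted p of 0.919 and a direction opposite to its median in camera.

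Scores of whole lists gave 0 of 46 past the threshold by the exact permutation test. A list alone at the smallest p this test can give, 0.005, could not pass over 46 lists. The lowest p was 0.045, for fatty acid oxidation and ketogenesis, with an adjusted p of 0.54. Its score was 6.81 ± 0.11 (SD, n = 6) in high FE and 6.99 ± 0.14 (SD, n = 6) in low FE, by the exact permutation test within sex. Smooth muscle had an exact permutation p of 0.13.

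Between males and females, 7 probe sets passed. EIF2S3, the X-linked subunit of a translation initiation factor, was lower in males, at 5.85 ± 0.19 (SD, n = 6) against 6.75 ± 0.17 (SD, n = 6), a difference of -0.91 ± 0.12 (SE) with an adjusted p of 0.0248. That call was lost in 10 of the 12 fits that left out 1 pig, with adjusted p up to 0.112 and a difference between -0.97 and -0.86 over the 12 fits, and kept without low FE pig 2 or high FE pig 6. With the run of pig identifiers as a term the difference was -0.87, with an adjusted p of 0.896; the 4 pigs of the second run are all female, so this term and sex are largely confounded. A probe set annotated as KDM6A, an X-linked histone demethylase, was higher in males by 3.13 ± 0.24 (SE), with an adjusted p of 2.21e-04. It had 5.97 ± 0.33 (SD, n = 6) in males and 2.84 ± 0.54 (SD, n = 6) in females, the latter close to the array background. The probe sets annotated as KDM6A disagreed, with differences of 3.13, 1.34, -0.50 and -1.13. The brightest had 6.68 ± 0.12 (SD, n = 6) in males and 7.19 ± 0.27 (SD, n = 6) in females and did not pass, with an adjusted p of 0.975. Females thus had signal well above the background medians from the brightest probe set and little from the one that passed. The latter is therefore not taken as a measure of KDM6A, and what it measures was not tested. The KDM6A probe set that passed and the unnamed ones below lie outside the naming rule and were singled out after their values were seen.

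The 5 other probe sets that passed have no symbol here. The brightest in females, SNOWBALL_037083_st, had 1.79 ± 0.31 (SD, n = 6) in males and 8.06 ± 0.85 (SD, n = 6) in females, a difference of -6.27 ± 0.34 (SE) with an adjusted p of 7.11e-06. SNOWBALL_035896_st was higher in males, at 4.47 ± 0.63 (SD, n = 6) against 1.67 ± 0.48 (SD, n = 6). The lower mean of either lies under the background medians of all 12 arrays, so the sizes of these differences are set by background at their lower end. Either probe set separated all 6 males from all 6 females. Both were picked by their difference between these same labels and have no symbol here. Their separation is therefore no check of the sex labels. The probe set annotated as the Y-linked EIF1AY had 7.01 ± 0.16 (SD, n = 6) in males and 7.43 ± 0.24 (SD, n = 6) in females. Females carry no Y chromosome, so it is no measure of a Y-linked transcript and no check of the sex labels. SRY lay below the filter at 1.18 ± 0.20 and 1.35 ± 0.16. XIST is not named in the array annotation used here.

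Other genes ranked for sex did not pass. With more signal in males, SCD, which desaturates fatty acids, had 6.95 ± 0.53 (SD, n = 6) against 5.56 ± 0.74 (SD, n = 6), and HYOU1, a chaperone of the endoplasmic reticulum, 8.63 ± 0.16 against 8.11 ± 0.14. SCD passed when adjusted over the fatty acid synthesis list alone, at 0.0196, and HYOU1 over the endoplasmic reticulum stress list alone, at 0.0143. ZNF202, SSR1, POP4 and SUV39H2, each of the last 2 with another probe set of opposite sign, the microRNA precursor ssc-mir-29c and 1 gene with a locus name only complete the 8. With less signal in males were CHN1, at -1.15 ± 0.23 (SE) with an adjusted p of 0.647 and a mean of 2.69 in males, close to the background, WNT11, a secreted WNT ligand, at -1.34 ± 0.32 (SE), TRPC4, CTBS, ABCA3, ZFX and 1 gene with a locus name only.

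Of 46 lists, 10 passed camera's test for sex, 5 higher and 5 lower in males. Interferon response genes were lower in males for 32 of 36 members, with a median of -0.22 and an adjusted p of 4.25e-05 (adjusted p = 0.749 with an estimated correlation). IFIT3 differed by -0.63 ± 0.18 (SE) and GBP2 by -0.79 ± 0.31 (SE). Fibroblast and extracellular matrix genes were higher in males for 23 of 29 members, with a median of 0.21 and an adjusted p of 3.20e-04 (adjusted p = 0.717 with an estimated correlation), among them SPARC at 0.32 ± 0.15 (SE) and COL4A2 at 0.27 ± 0.12 (SE). Endoplasmic reticulum stress genes were higher for 20 of 26, with a median of 0.16 and an adjusted p of 4.83e-04 (adjusted p = 0.459 with an estimated correlation). The X homologues of Y-linked genes were lower for 7 of 10, with a median of -0.27 and an adjusted p of 9.94e-04 (adjusted p = 0.593 with an estimated correlation), and EIF2S3, ZFX and the brightest KDM6A probe set passed when adjusted over the list alone, where over all probe sets EIF2S3 did. The other ZFX probe set differed in the opposite direction. With the mean of all probe sets of a gene this list had an adjusted p of 0.40 and a median of -0.15, and the median was -0.17 without low FE pig 3 and -0.42 with the array background as a term. The interferon median was -0.14 without high FE pig 4 or with the Brunner gland score as a term and -0.37 without low FE pig 1, and that of endoplasmic reticulum stress was 0.09 without high FE pig 3.

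Fatty acid synthesis was higher in males, with a median of 0.11 and an adjusted p of 0.00582 (adjusted p = 0.399 with an estimated correlation), and 0.052 without high FE pig 5. Its median lay between 0.06 without high FE pig 5 and 0.20 without high FE pig 1, also moved by over 1.5 times without high FE pig 6 or low FE pig 3, 4 or 6, and was 0.18 with the array background as a term. Cholesterol synthesis, with a median of 0.19 and an adjusted p of 0.0217, and cell proliferation, with 0.10 and 0.0445, were higher (adjusted p = 0.749 each with an estimated correlation). Mature enterocyte, with -0.14 and 0.0265, xenobiotic metabolism, with -0.10 and 0.0352, and pancreatic acinar genes, with -0.48 and 0.00582, were lower (adjusted p = 0.749 each with an estimated correlation). All 5 calls were lost with that correlation. NSDHL of cholesterol synthesis differed by 0.42 ± 0.19 (SE), CDC6 by 0.54 ± 0.16 (SE), and PCK1, a gluconeogenic enzyme of enterocytes, by -0.75 ± 0.32 (SE). Without low FE pig 6 the pancreatic median was -0.07, with an adjusted p of 0.354, and proliferation had an adjusted p of 0.165. With the array background as a term the adjusted p was 0.0605 for cholesterol synthesis, 0.179 for pancreatic acinar genes and 0.571 for proliferation. The cholesterol call also ended without high FE pig 3, 5 or 6, with adjusted p up to 0.298 and medians of 0.09 without high FE pig 3 and 0.12 without high FE pig 6. The mature enterocyte call ended without high FE pig 2, 4 or 6 or low FE pig 3, 4 or 5, with adjusted p up to 0.222, and with the Brunner gland score as a term, at 0.309, where the median turned to 0.002, or with the mean of all probe sets of a gene, at 0.0758, with a median of -0.23. That median moved by over 1.5 times without high FE pig 2, 5 or 6 or low FE pig 1, 3 or 6, from -0.27 without low FE pig 6 to -0.0625 without high FE pig 2, and was -0.22 with the array background as a term. The xenobiotic call ended without those 6 pigs or high FE pig 1, with adjusted p up to 0.24, with no filter, at 0.0956, and with the Brunner gland score as a term, at 0.179. The xenobiotic median moved by over 1.5 times without high FE pig 3 or 6 or low FE pig 1 or 6, from -0.17 without low FE pig 6 to -0.0472 without high FE pig 6, and was -0.0590 with no filter and -0.15 with the array background as a term. The proliferation call also ended without high FE pig 1, 3, 5 or 6 or low FE pig 1, with adjusted p up to 0.649, and with arrays centred on their median, at 0.053. The proliferation median moved by over 1.5 times without high FE pig 2 or low FE pig 1, 3 or 6, from 0.0595 without low FE pig 1 to 0.173 without high FE pig 2, and was 0.186 with the Brunner gland score as a term. The pancreatic median was -0.30 with the median filter and -0.21 with the array background as a term. Over whole scores by sex, 0 of 46 lists passed the exact permutation test, and the lowest p, for endoplasmic reticulum stress, was 0.005, the smallest it can give, with an adjusted p of 0.23. A list alone at that p cannot pass over 46 lists, so not passing does not speak against a difference in that list.

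The FE difference itself differed between the sexes for 1 gene. CYP39A1, an oxysterol hydroxylase of bile acid synthesis, had 2.00 ± 0.08 (SD, n = 3) in high FE males and 4.23 ± 0.46 (SD, n = 3) in low FE males, against 4.15 ± 0.18 (SD, n = 3) in high FE females and 1.76 ± 0.78 (SD, n = 3) in low FE females. The interaction was -4.62 ± 0.48 (SE) with an adjusted p of 0.0327. The gene has 1 probe set, and the lower means lie under the background medians of all 12 arrays, so the sizes of its differences are set by background at their lower end. The call was lost in 10 of the 12 fits that left out 1 pig and kept without low FE pig 2 or low FE pig 6. It was also lost with array weights (adjusted p 0.0939), the identifier run (0.0875) or the array background (0.0954) as a term, and the ordinary linear model (0.38). Over the alternatives in which the gene was tested, its interaction lay between -5.05 and -4.28 and its adjusted p between 0.00159 and 0.38.

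**Figure D2:**
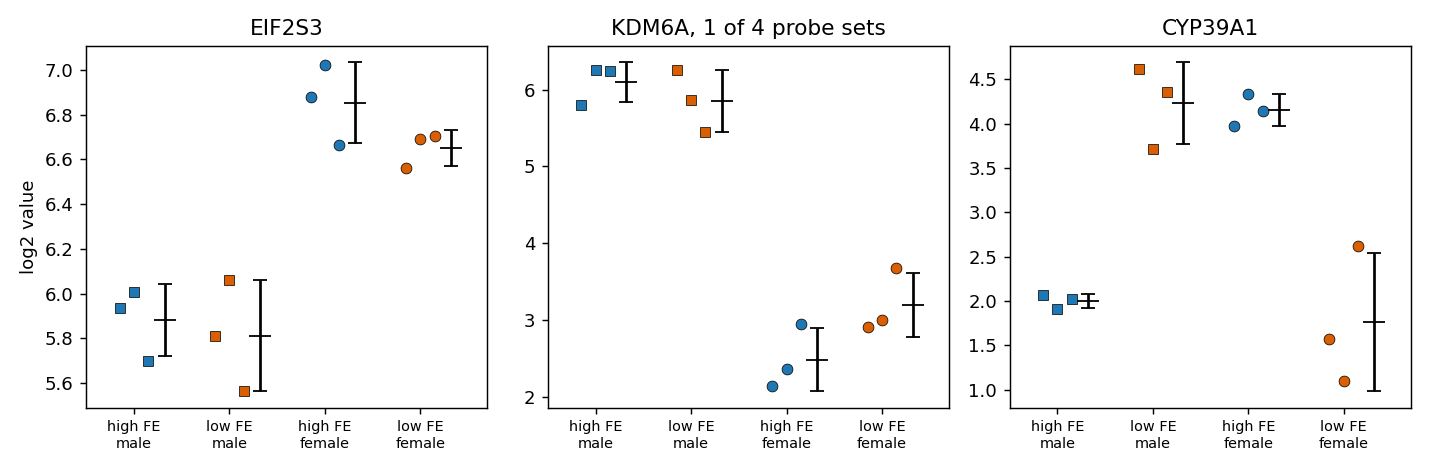
Log2 values of EIF2S3, of the KDM6A probe set that passed and of CYP39A1 in the 4 combinations of FE and sex; each point is a pig (squares males, circles females, blue high FE, orange low FE) and bars are means with the SD (n = 3). EIF2S3 is higher in all females than in all males, and CYP39A1 is high in low FE males and high FE females.

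The other genes ranked for the interaction did not pass, with an adjusted p of 0.998 each. DUOX2, which makes hydrogen peroxide at the epithelial surface, had an interaction of 2.09 ± 0.57 (SE), and MMP28, an epithelial metalloproteinase, of 1.25 ± 0.27 (SE). TBPL2, NRSN2, with 1 of 2 other probe sets of opposite sign, and 1 gene with a locus name only were also positive. SERPINA7, a thyroxine-binding globulin, had -2.90 ± 0.58 (SE), of which the lower means, 1.80 and 1.61, lie under the background medians. MPV17, a protein of the inner mitochondrial membrane, had -2.65 ± 0.54 (SE), with a low FE female mean of 2.59 close to the background, and UNC45B and FANCG were negative too. At an unadjusted p under 0.05 there were 1094 probe sets, fewer than the 1670 expected by chance.

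Within males, 0 probe sets passed in limma or in an ordinary linear model, and 1873 had an unadjusted p under 0.05. Chance gives about 1670. CYP39A1 differed by -2.23 ± 0.34 (SE), with an adjusted p of 0.652, and the microRNA precursor MIR29C by 1.78 ± 0.33 (SE), with an adjusted p of 0.812, where the low FE male mean of 1.75 lies under the background medians, as does that of MIP, 2.10. MIP, PKD2L1 and ITGB1BP2, whose other probe set had the opposite sign, had more signal in high FE males, and Mir345, FBXL8 and UNC45B less. Within females, 0 probe sets passed in limma or in an ordinary linear model. There, 1225 had an unadjusted p under 0.05, fewer than the 1670 that chance gives. CYP39A1 differed by 2.39 ± 0.34 (SE) and MPV17 by 2.47 ± 0.38 (SE), each with an adjusted p of 0.547. The low FE female mean of CYP39A1, 1.76, lies under the background medians and that of MPV17, 2.59, close to them. RAP1GDS1 and ZNF883 had more signal in high FE females, and YTHDF1, MMP28, CAMK2B and MAP7D3 less. Without low FE pig 6, CYP39A1 passed within females, at 2.82 with an adjusted p of 0.026.

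**Figure D3:**
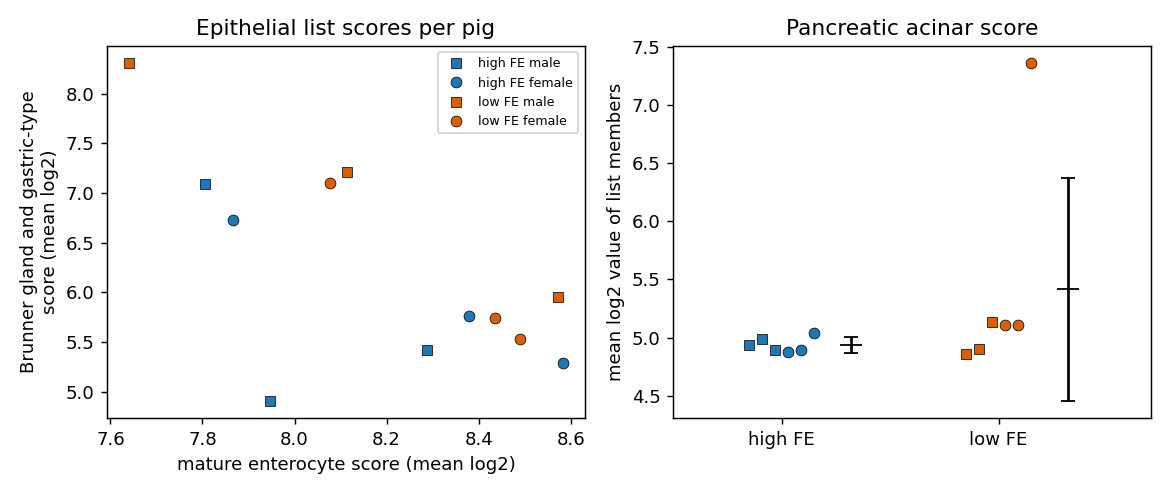
Left, the score of Brunner gland and gastric-type genes (vertical axis, mean log2) against the mature enterocyte score (horizontal axis, mean log2), each point a pig; right, the pancreatic acinar score (mean log2) by FE group with the mean and SD beside each group. The Brunner gland and gastric-type score runs from 4.90 to 8.31, and the acinar score of 1 low FE pig stands at 7.36.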

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

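Of the tests on the acinar transcripts below, those on feed efficiency and on a shift of the whole array were chosen after the result was seen. Dixon's test was run on 176 groups of 6 pigs, over list scores, named genes, array background and the first principal component. It picked out 10 values, where chance gives about 1 in 20 groups, or 8.8.

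Low FE pig 6 had a pancreatic acinar score of 7.36, far from the other low FE pigs, whose highest was 5.13. CPA1, a carboxypeptidase, stood at 8.71 in this pig and at most at 3.64 in the others, PLA2G1B at 9.09 against 4.51, CTRL at 7.89 against 4.52, and CLPS at 6.98 against 4.15. Of 16 measured genes, 10 exceeded every other pig by more than 1 on the log2 scale. SPINK1 and PNLIPRP2 did not, at up to 12.64 and 10.93 in the other pigs, and CELA1, CTRC and RBPJL were not highest in this pig either. SYCN exceeded the highest of the other pigs by 0.35.

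A shift of the whole array is argued against, since 0% of 10000 random lists matched on mean signal stood as far above the other pigs as the list's median of 2.85. Pancreatic tissue in the sample is a candidate source that its own test left undecided. A second list of acinar genes, written before its values were seen, had 6 of 14 names measured and a median of 0.27 with an SD of 0.42, below the value of 0.3 that had been set beforehand as speaking against it, though by less than that SD, and that such a shortfall leaves the question undecided was settled after this value was seen. In that list ERP27, at 1.08 above the mean of the other pigs, TMED6, at 0.47, and BHLHA15, at 0.30, stood above every other pig, and PDIA2, GNMT and SLC43A1 did not. Feed efficiency stays open on the test used, as 4 low FE pigs exceeded every high FE pig by more than the high FE SD of 0.07, but 3 of them by at most 0.10, against 2.32 in low FE pig 6.

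CYP39A1 differed in its FE effect between the sexes, with an interaction of -4.62, -2.23 in males and 2.39 in females, where the lower means lie under the array background medians. In 6 of 100 splits of the pigs within sex at least 1 probe set passed for the interaction, with 1 in the real split and 6 as the highest of the others, so chance cannot be excluded.

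Low FE pig 1 had a smooth muscle score of 7.155, where the next low FE pig had 7.84, an enteric neuron and glia score of 4.79 against 5.08, and an HSPB6 value of 7.92 against 8.735. High FE pig 1 had an electrolyte, bicarbonate and water transport score of 6.31 against 6.73, and an MRPS30 value of 6.62 against 6.22. High FE pig 6 had a ribosomal protein score of 8.23 against 7.99 and an adipocyte score of 5.785 against 5.34. NDP stood at 2.46 in high FE pig 5, with the next at 3.13. HYOU1 stood at 8.94 in high FE pig 3, with the next male at 8.61.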

How the results depend on the processing

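The fits with array background, with the Brunner gland score and without 3 arrays were chosen after seeing the data, as were those of named genes under other filters, the ordinary linear model and 1 probe set per gene symbol. The FE effect had 0 probe sets past the threshold in every fit with all pigs, and 0 to 1 when 1 pig was left out; without low FE pig 4, a dim probe set of AAMP, singled out after its value was seen, passed at -1.41. The sex effect had 7 probe sets, 1 with 1 probe set per gene symbol, 3 with the run of pig identifiers as a term (largely confounded with sex, as the second run holds 4 females and no males), and 6 to 8 with 1 pig left out. With 1 probe set per gene symbol, the unnamed probe sets and the KDM6A one that passed were not tested. That lower count is therefore no loss of their calls. The interaction had 1, and 0 with the median filter, array weights, the ordinary linear model, the identifier run or the array background (CYP39A1 does not pass the median filter), and 0 to 1 with 1 pig left out. Within females there were 0 to 1 with 1 pig left out. Lists past the threshold for FE numbered 6, against 0 with an estimated correlation, 0 with fry, 16 (11 of them higher) without the 3 arrays lowest on the first principal component (all of high FE), and 1 to 9 with 1 pig left out. Counts were 3 without high FE pig 1, high FE pig 3 or low FE pig 6, and 1 without high FE pig 4. For sex there were 10 lists, against 0 with an estimated correlation, 0 with fry, and 6 to 18 with 1 pig left out, the 6 without high FE pig 6 and the 18 without low FE pig 1. Signs turned for CELA2A by sex with the identifier run, at 0.0416, for ALOX5AP by FE and PNPLA2 by sex with the array background, at 0.125 and 0.0189, for the cell proliferation list by FE with the Brunner gland score as a term, at -0.0567, and for oxidative phosphorylation by FE without the 3 arrays, at 0.0159. The medians, though not camera's directions, also turned for proliferation by FE without high FE pig 4, at -0.0035, and mature enterocyte by sex with the Brunner gland score, at 0.002. Of the values of single genes under the alternatives, 2514 for FE and 2216 for sex kept their direction and side of the threshold, and 11 for sex lost their call. No gene followed for FE passed in the main fit or under an alternative, where the lowest adjusted p was 0.169 in limma, for MIP. For FE, keeping the side thus meant not passing. All 11 losses were of EIF2S3, the only gene followed for sex that passed in the main fit. Many of these genes were picked by low p in the same data, so the counts kept say little on how firm their differences are. Of those of lists past the threshold, 86 were kept and 44 lost for FE, and 157 kept and 53 lost for sex. What caused these losses was not tested, and this includes the number of probe sets tested and the number of pigs. Signal over background limits dim genes, since the median background per array lay between 2.16 and 2.53. Single background probe sets had means of up to 7.62, so this limit can also reach genes above those medians. No paired analysis was possible because the labels give no replicate numbers shared between groups, and the numbers used here follow only the order of the samples.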

Other observations

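The tests on the Brunner gland and gastric-type genes and on the first principal component were chosen after the scores were seen.

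Genes of Brunner glands and gastric-type epithelium varied more between pigs than any other of the 46 lists, with scores from 4.90 in high FE pig 1 to 8.31 in low FE pig 3. GKN1, a secreted protein of gastric surface cells, ranged from 3.27 to 12.17, GKN2 from 2.62 to 11.10, the gastric mucin MUC5AC from 6.19 to 12.42, and the trefoil peptide TFF2 from 9.80 to 13.64. PSCA, ATP12A, DUOX1 and PIK3C2G of the same list ranged over at most 1.57. By FE the list's median was -0.55, with an adjusted p of 0.202.

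Interferon response scores went with mature enterocyte scores over the 12 pigs, with a Pearson r of 0.82 (permutation p = 0.00167) and a Spearman rho of 0.80 (permutation p = 0.0025). Adjusted over the 7 relations computed, these are 0.00585 and 0.00875, which does not cover the other pairs possible among the 46 list scores. Without high FE pig 2 and low FE pig 3, the farthest from the median enterocyte score, r was 0.72. Within high FE r was 0.75 and within low FE 0.90 (exact permutation p = 0.0958 and 0.00417, n = 6 each), and among the 8 pigs of the lower identifier run 0.77 (permutation p = 0.0268). The other run has 4 pigs, too few for a value. The relation is not shown to be particular to interferon response. Scores of T and NK cells and of carbohydrate digestion lay above their means in the same pigs as the mature enterocyte score. The interferon score did not do so in high FE pigs 1 and 3 and low FE pig 4. Correlations of those other scores with the mature enterocyte score were not computed.

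A larger share of gastric-type tissue in some samples is a candidate explanation of the spread in the Brunner gland score, since it was lower where the mature enterocyte score was higher over 12 pigs, with a Pearson r of -0.69 (permutation p = 0.0151, adjusted 0.0264) and a Spearman rho of -0.55 (permutation p = 0.0723, adjusted 0.164). The relation rests on high FE pig 2 and low FE pig 3, without which r was -0.41 (permutation p = 0.235). Within high FE r was -0.59 and within low FE -0.97 (exact permutation p = 0.251 and 0.0139, n = 6 each), and among the 8 pigs of the lower identifier run -0.61 (permutation p = 0.106). Array background stays open, with r = 0.28 (permutation p = 0.377), and so does feed efficiency, with an exact permutation p of 0.20.

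The first principal component held 24.9% of the variance and followed the array background, with r = 0.93 (permutation p = 2e-05) and a Spearman rho of 0.95 (permutation p = 2e-05), each 1.4e-04 adjusted over 7 relations. Without high FE pig 5 and low FE pig 6 r was 0.91, and it was 0.96 within high FE and 0.90 within low FE (exact permutation p = 0.00278 and 0.00694, n = 6 each). Array background is therefore a candidate source of this component, although a difference in RNA could set both. Tissue makeup stays open, with r = 0.21 (permutation p = 0.51) against the Brunner gland score, and feed efficiency too, with an exact permutation p of 0.15.

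Regroupings of the pigs within sex, 100 in all, gave as many probe sets at an unadjusted p under 0.05 as the real 2000 for FE in 20, with 5168 as the highest of the others, so chance is not excluded. A structure of the samples is a candidate source of so high a count, but none was identified and this was not tested. For lists by FE, 53 of 100 gave at least 6, with 25 as the highest other, and for lists by sex 43 of 100 gave at least 10, with 23 as the highest other, so chance is excluded for neither. Splits by sex were drawn within FE groups. For probe sets by sex, 1 of 100, the real split, gave 7, and the highest other gave 1, so chance is unlikely to give this count. The share covers the count and no single probe set. The 10 splits of 6 males or 6 females are too few for a share under 0.05. For males the real count was 1873 and the highest other 2961, with 3 splits as large, and for females 1225 and 3368, with 6 splits as large.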
